A study of Mus musculus with 12 samples.

How the data were processed

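Liver RNA of mice on a mixed SV129 and C57Bl/6 background was measured on an Affymetrix mouse expression array. Per the labels' protocols, each of the 12 arrays carried biotin-labelled cRNA from a pool of RNA of 3 animals. The arrays form 4 groups of 3, which cross genotype (control, or LG2KO and treated with tamoxifen) with feeding state (fasted, or fasted and then refed). The groups were taken from each sample's title, genotype and diet labels. There is 1 conflict among the labels. The source description of the LG2KO fasted arrays calls them fasted and refed, while their titles and diet labels say fasted, and the latter were used. Control arrays carry no tamoxifen label, so genotype and tamoxifen labels coincide in every genotype comparison.

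The deposited values are log2 expression values, 1 per probe set and array. Per the submitters' processing notes the authors made them with RMA, which corrects background, brings all arrays to a common distribution and summarises the probes of a set on the log2 scale. The software, its version and a genome build are not given in the sources used here. The 45101 probe sets were tied to genes through the platform's annotation. Of these, 34958 had 1 gene symbol, 932 had several and were left out of the gene tests, and 9211 were not listed in the annotation and are unnamed here. The symbols were compared through their Entrez numbers with the RefSeq table of mouse assembly GRCm38.p6, which changed 0 of them. Each symbol was represented by the probe set with the highest mean over all 12 arrays, which left 18194 genes, 9012 of them with more than 1 probe set. Of the 255 named values that passed the test, 13 came from genes with probe sets of both signs, and 0 had a probe set that passed in the opposite direction. Some genes are not reported here. No filter on dim genes was applied in the main tests, and the number of arrays limits the precision.

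Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 1 mean per group, all 12 arrays in the fit and 8 residual degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all 18194 genes within each comparison, and an adjusted p below 0.05 counts as passing. The p-values reflect the spread between pools. The 6 comparisons were LG2KO against control after refeeding, LG2KO against control in the fasted state, refed against fasted in each genotype, the interaction of genotype and feeding, and the genotype difference averaged over the feeding states. Errors of log2 fold changes are standard errors from this fit. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

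The groups, tests, alternatives, gene lists and the rule for naming genes were set before the data were examined. The 31 lists hold 530 members, of which 475 were measured. They cover cholesterol synthesis, sterol uptake and its regulators, fatty acid synthesis, genes linked to the glucose-responsive factor ChREBP, glycolysis, gluconeogenesis with amino acid catabolism, glycogen, fatty acid oxidation with PPARalpha targets, bile acid synthesis, bile acid transport, hexose transporters, insulin signalling, lipoproteins with triglyceride handling, xenobiotic metabolism, cell cycle, the unfolded protein and integrated stress response, acute phase, interferon, circadian clock, male-biased and female-biased liver genes and sex chromosome transcripts. They also cover markers of hepatocytes, macrophages, endothelium, stellate cells and fibroblasts, cholangiocytes, lymphocytes and neutrophils, erythroid cells, adipose tissue and exocrine pancreas. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the 31 lists within a comparison, and again with an estimated correlation. Named genes are Slc2a2, the 10 largest rises and 10 largest falls per comparison among genes that passed with groups of arrays that do not overlap, and up to 4 members with the smallest adjusted p of each list that passed or had at least 3 members passing. Clone-like symbols were left out of the largest changes. Some genes could be named whether or not they passed. In every refeeding comparison these were Pklr, Fasn, Srebf1, Pck1, Cpt1a and G6pc. In every genotype comparison they were Txnip, Pklr, Sqle, Cyp7a1, Cyp8b1, Fasn, G6pc, Srebf1 and Srebf2.

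The fit was tested on simulated data with 200 changed genes of known fold change among the 18194. For LG2KO against control after refeeding it found 46.3% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 97.0% of those changed 4-fold, with 4 false calls. For the interaction it found 11.9%, 65.7% and 90.9%, with 5 false calls. False calls were highest for LG2KO against control in the fasted state, at 10, and for refeeding in LG2KO, at 11. The simulated noise was drawn independently for each gene and array, so no simulated array lay far from its group as a whole. Alternatives were a prior without the intensity trend or with robust estimation, a fit of only the groups compared, the replicate number as a block, array weights, centring each array on its median, cyclic loess, only the brightest genes by mean at either of 2 limits, the mean of all probe sets of a gene, every probe set, a fold threshold of 1.5, an adjusted p below 0.01, leaving out each array in turn, and for lists an estimated correlation and limma's fry. Added after seeing the data were the fit without the pair of arrays that stand apart, the ChREBP-linked list without Slc2a2, and a list of p53 targets.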

Results

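Expression was measured in the livers of control mice and of mice labelled LG2KO. The labels do not spell out that name, which is read here as a knockout of the hepatic glucose transporter Glut2, encoded by Slc2a2. The series asks what glucose sensing by the liver contributes to the ability of beta cells to respond to glucose, and the arrays cover the liver side of that question. There were 3 arrays in each of 4 groups: control fasted, LG2KO fasted, control refed and LG2KO refed. Each array held a pool of RNA from 3 animals, so n = 3 pools per group below. The control arrays carry no tamoxifen label and the LG2KO arrays do. Arrays of 1 group correlated with each other at 0.984 to 0.996 across probe sets.

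Slc2a2 transcript fell by 7.21 ± 0.25 on the log2 scale in refed LG2KO livers (adjusted p = 2.26e-08) and fell by 6.73 ± 0.25 in fasted ones (adjusted p = 5.21e-08). Its level was 10.96 ± 0.32 (SD, n = 3) in refed controls and 3.74 ± 0.09 in refed LG2KO livers, and 10.64 ± 0.56 and 3.90 ± 0.30 in the fasted state. All 6 LG2KO arrays lay below all 6 control arrays, at the 24.9 to 38.8 percentile of their array. Background is not known at that level, so the size of the fall is uncertain. The gene was read by 1 probe set, whose place relative to the deleted part is not given in the sources used here.

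**Figure D1:**
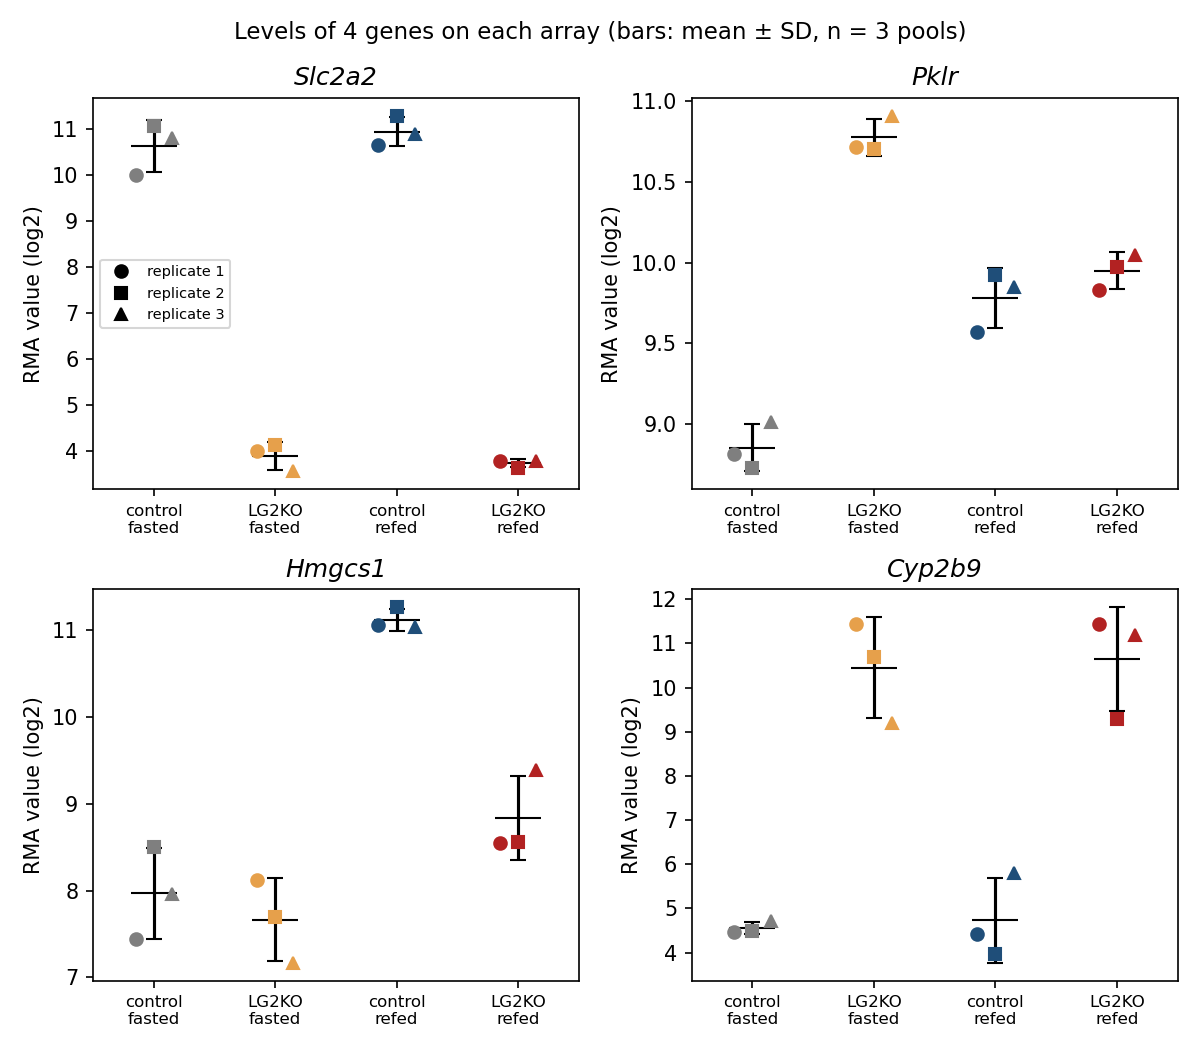
Log2 expression of Slc2a2, Pklr, Hmgcs1 and Cyp2b9 on each of the 12 arrays by group, with replicates as symbols and bars for the mean and SD of 3 pools. Pklr was 8.85 in fasted controls and 10.77 in fasted LG2KO livers, and Hmgcs1 was 11.12 in refed controls and 8.83 in refed LG2KO livers.

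Principal components were computed on the genes whose mean over the arrays lay above the median of all genes. The first component, with 40.2% of the variance, ran from fasted to refed arrays. Close to its middle lay control refed replicate 1 at -1.52 and LG2KO fasted replicate 3 at -5.31. The second component, with 28.1%, was set by control refed replicate 1 at 37.1 and LG2KO fasted replicate 3 at -31.4, while the other arrays lay between -11.4 and 7.46. Without this pair the lowest correlation within a group was 0.994. A further array, control fasted replicate 3, carried transcripts of exocrine pancreas, such as Ctrb1 at 9.18 against at most 5.51 on any other array.

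**Figure D2:**
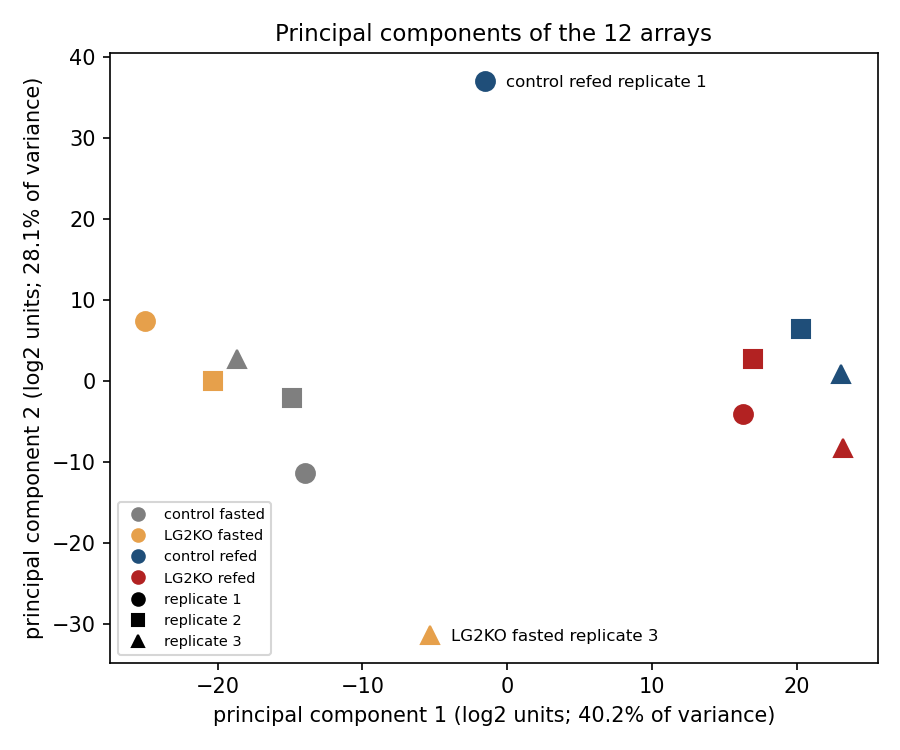
Position of each array on the first principal components, in log2 units, over genes whose mean lay above the median of all genes. Arrays are coloured by group with replicates as symbols. Control refed replicate 1 and LG2KO fasted replicate 3 lie at opposite ends of the second component.

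In refed livers cholesterol synthesis enzymes were lower in LG2KO. Idi1, which makes the isoprenoid building block of sterols, fell by 2.69 ± 0.32 (6.45-fold, adjusted p = 0.00516), and Hmgcs1, which makes HMG-CoA, fell by 2.29 ± 0.30 (4.88-fold, adjusted p = 0.0103). The sterol-modifying enzymes Msmo1, Cyp51 and Hsd17b7 fell by 1.98 ± 0.26, 1.78 ± 0.31 and 1.19 ± 0.22. Of 17 measured enzymes of this list 6 fell, 16 did so when adjusted over the list alone, and all 17 had negative fold changes, with a median of -1.22 (camera, adjusted p = 5.34e-28, and adjusted p = 0.0381 with an estimated correlation). Squalene epoxidase, Sqle, was at -1.52 ± 0.38 with an adjusted p of 0.143. The transcription factor gene Srebf2, which drives this pathway, was at -0.14 ± 0.13 with an adjusted p of 0.813. Without the arrays that stand apart 12 of the 17 enzymes fell, with a median of -1.64.

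The largest rise in refed LG2KO livers was that of the cytochrome P450 gene Cyp2b9, by 5.92 ± 0.63 (adjusted p = 0.00366). Its relative Cyp2b10, a usual target of the xenobiotic receptor CAR, rose by 1.78 ± 0.32. Lcn2, an acute phase protein, rose by 2.84 ± 0.48 and Lbp, which binds bacterial lipopolysaccharide, by 0.57 ± 0.08. These 2 were the members of 26 acute phase genes that passed, and 3 did when adjusted over the list alone. The median of that list was 0.31 (camera, adjusted p = 9.42e-08, and adjusted p = 0.22 with an estimated correlation). Other rises were Mmd2 at 2.11 ± 0.39, Eci3, an enzyme of fatty acid oxidation, at 2.08 ± 0.37, Dct at 1.86 ± 0.31, the prostaglandin synthase Ptgds at 1.64 ± 0.24, the cell cycle inhibitor Cdkn1a at 1.59 ± 0.27 and Kbtbd11 at 1.04 ± 0.18. The complement gene C6 fell by 1.11 ± 0.17 and Cib3 fell by 1.18 ± 0.19.

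Genes of sex-dependent liver metabolism moved as well. Of 9 measured male-biased genes, Hsd3b5 fell by 1.85 ± 0.34 and Cyp4a12a fell by 1.49 ± 0.24, and 4 fell when adjusted over the list alone. The median of the list was -0.58 (camera, adjusted p = 1.45e-10, and adjusted p = 0.0381 with an estimated correlation), and without the arrays that stand apart 0 passed over all genes while the median was -0.53 (camera, adjusted p = 1.41e-07). Leaving out 1 array gave medians from -0.96 (without LG2KO refed replicate 2) to -0.39, and the list passed each time. Relative to all arrays its genes lay on average at -0.59, 0.13 and 0.02 on LG2KO refed replicates 1, 2 and 3. On control refed replicates 1, 2 and 3 they lay at 0.77, 0.73 and 0.52. The size of the fall thus leans on LG2KO refed replicate 1. The 11 female-biased genes had a median of 0.23, with Cyp2b9 the member that passed, 5 higher and 1 lower when adjusted over the list alone (camera, adjusted p = 0.008, and adjusted p = 0.235 with an estimated correlation). Of 23 xenobiotic metabolism genes Cyp2b10 rose and the glutathione transferase Gsta4 fell by 0.80 ± 0.14. That list had a median of -0.16 (camera, adjusted p = 0.00123, and adjusted p = 0.0381 with an estimated correlation), with 1 higher and 3 lower when adjusted over the list alone.

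Smaller shifts touched glucose and lipid metabolism in the refed state. Srebf1, a transcription factor of lipid synthesis, rose by 0.89 ± 0.10 (adjusted p = 0.00499), and the lipid droplet gene Pnpla3 by 1.03 ± 0.15. These were the 2 of 20 fatty acid synthesis genes that passed, with 5 when adjusted over the list alone and a list median of 0.20, or 0.125 without control refed replicate 3 (camera, adjusted p = 0.00772, and adjusted p = 0.22 with an estimated correlation). Of 15 ChREBP-linked genes the fructokinase gene Khk, at 0.61 ± 0.08, and Pnpla3 rose and Slc2a2 fell, against 4 higher and 1 lower when adjusted over the list alone. The test of this list was upward with a median of 0.17 while its mean was -0.20, because it holds Slc2a2 (adjusted p = 0.0146, and adjusted p = 0.129 with an estimated correlation). Without Slc2a2, a test added after seeing the data, the median was 0.24 and the mean 0.30. The camera p there, not adjusted over lists, was 6.74e-06, and 0.00138 with an estimated correlation. Leaving out single arrays was not tried without Slc2a2. In gluconeogenesis and amino acid catabolism 3 of 18 genes rose, namely pyruvate carboxylase, Pcx, by 0.60 ± 0.07, argininosuccinate lyase, Asl, by 0.40 ± 0.07 and Fbp1 by 0.22 ± 0.04, and also 3 when adjusted over the list alone (camera, adjusted p = 0.00772, and adjusted p = 0.417 with an estimated correlation). Of 20 stress response genes Trib3 rose by 0.71 ± 0.13 and Atf4 fell by 0.45 ± 0.09, with 7 higher and 1 lower when adjusted over the list alone (camera, adjusted p = 0.000941, and adjusted p = 0.166 with an estimated correlation). Pklr, Fasn, Txnip and G6pc were at 0.17 ± 0.12, 0.27 ± 0.16, 0.04 ± 0.13 and 0.37 ± 0.15, and Cyp7a1 and Cyp8b1, of bile acid synthesis, at -0.33 ± 0.55 and -0.14 ± 0.15, none of which passed.

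No member passed in 2 further lists with a camera call. The test of 22 genes of fatty acid oxidation was downward, with 4 lower when adjusted over the list alone (adjusted p = 2.35e-06, and adjusted p = 0.243 with an estimated correlation). The test of 14 macrophage markers was upward, with 0 when adjusted over the list alone (adjusted p = 0.0425, and adjusted p = 0.717 with an estimated correlation).

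In total 69 of 18194 genes passed in refed livers, 53 higher and 16 lower in LG2KO, and 1661 had an unadjusted p below 0.05. In all 69 the 3 arrays of each group did not overlap, which passing the test on the same arrays nearly fixes. The 10% that chance gives holds for genes taken without selection, so the lack of overlap adds no support. The count was 52 without the arrays that stand apart, of which 29 were higher and 31 were among the 69. It was 41 without the intensity trend, 43 with robust estimation, 180 with array weights, 121 in the top 25% of genes by mean and 15 when only these groups were fitted. Leaving out 1 array gave 35 genes without control refed replicate 1, 14 without replicate 2 and 23 without replicate 3, and 22 and 8 without LG2KO refed replicates 1 and 3. Slc2a2, Cyp2b9, Idi1, Srebf1 and Pcx passed without each array, while the other 24 of the 29 named genes that passed missed without at least 1 array: 18, 23 and 16 of them without control refed replicates 1, 2 and 3, and 18, 11 and 23 without LG2KO refed replicates 1, 2 and 3. The fatty acid synthesis and ChREBP-linked lists did not pass without control refed replicate 3 (adjusted p = 0.0614 and 0.0818), gluconeogenesis missed without LG2KO refed replicate 1 or control refed replicate 2 or 3 (at most 0.122), and macrophage markers without those 3 or LG2KO refed replicate 3 (at most 0.395).

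In the fasted state, where little glucose reaches the liver from food, several ChREBP-linked and fatty acid synthesis genes were higher in LG2KO. Liver pyruvate kinase, Pklr, which ChREBP switches on when glucose is plentiful, rose by 1.92 ± 0.12 (3.78-fold, adjusted p = 7.41e-06), from 8.85 ± 0.15 (SD, n = 3) to 10.77 ± 0.12. The fructose-pathway kinase genes Tkfc and Khk rose (Tkfc by 1.59 ± 0.13, each with an adjusted p of 0.000152), and glucose-6-phosphatase, G6pc, the last step of glucose release, by 1.19 ± 0.15. Of 15 ChREBP-linked genes 6 rose and Slc2a2 fell, with 10 higher and 1 lower when adjusted over the list alone and a median of 0.52 (camera, adjusted p = 4.60e-17, and adjusted p = 0.000418 with an estimated correlation). The ChREBP-linked gene Txnip was at 0.47 ± 0.13 with an adjusted p of 0.293.

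Fatty acid synthesis rose alongside in fasted LG2KO livers. The elongase Elovl6 rose by 1.98 ± 0.27 (3.94-fold, adjusted p = 0.00555), Thrsp by 1.84 ± 0.22, fatty acid synthase, Fasn, by 1.27 ± 0.16, malic enzyme, Me1, by 1.22 ± 0.12, citrate lyase, Acly, by 1.14 ± 0.13, Mid1ip1 by 1.08 ± 0.10 and acetyl-CoA carboxylase, Acaca, by 1.04 ± 0.11. Srebf1 rose by 0.62 ± 0.10. In all, 8 of 20 genes of this list rose, with 8 higher and 2 lower when adjusted over the list alone and a median of 0.30 (camera, adjusted p = 4.01e-14, and adjusted p = 0.00741 with an estimated correlation).

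**Figure D3:**
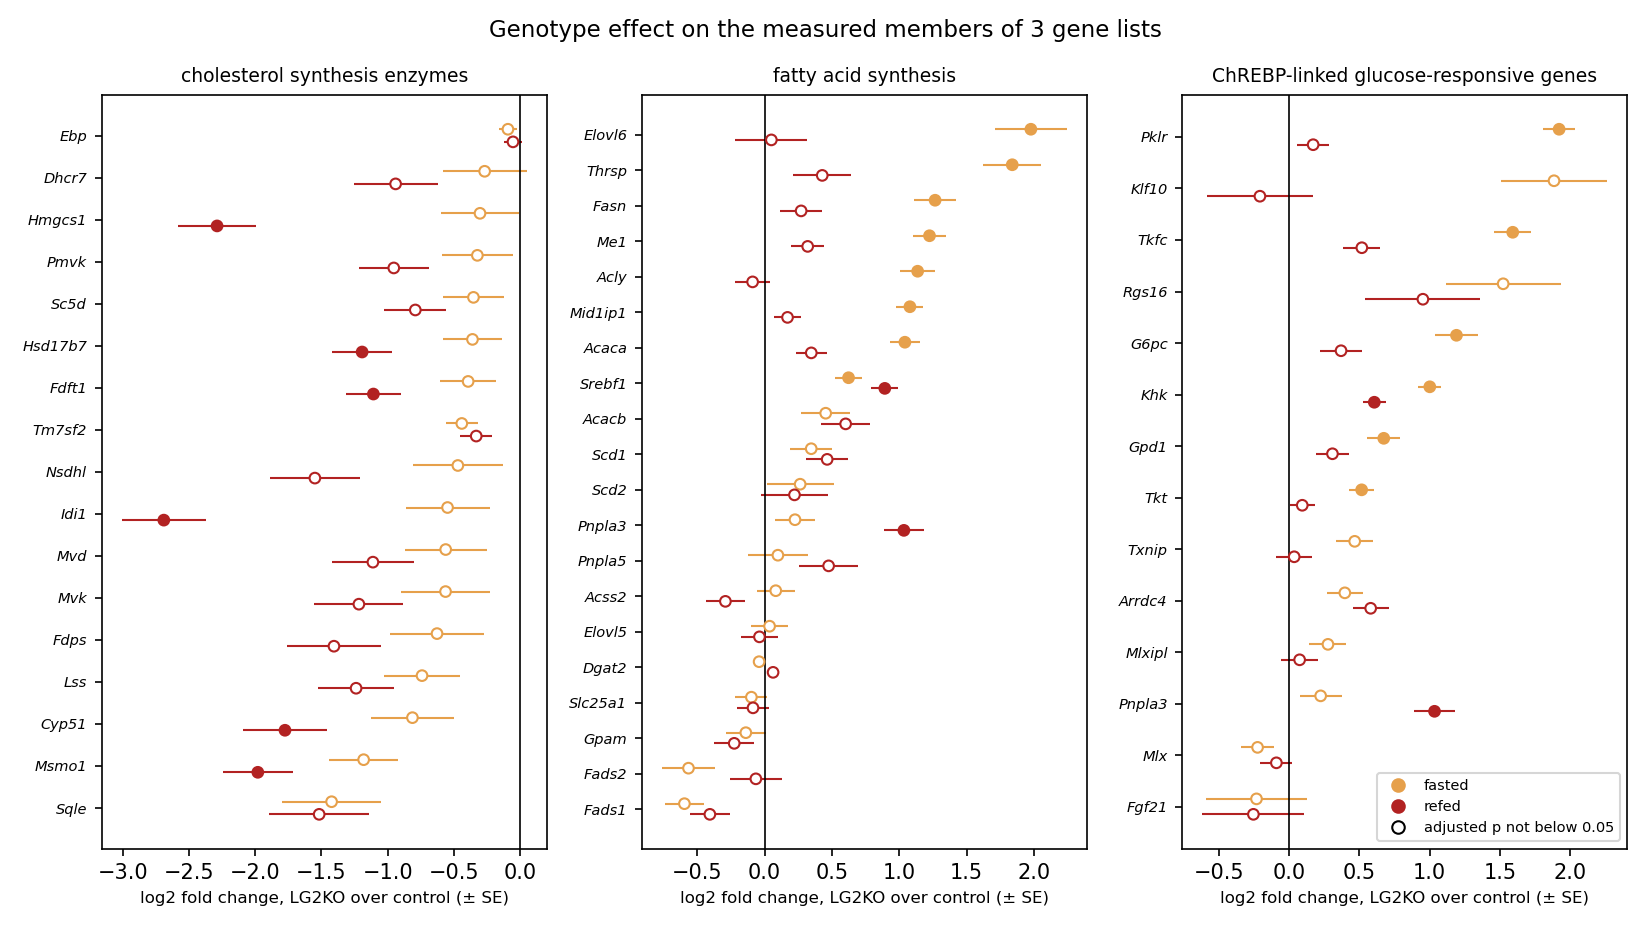
Log2 fold change (LG2KO over control, with standard error) of the measured members of 3 gene lists in fasted and refed livers, with filled points where the adjusted p was below 0.05. Slc2a2, a member of the third list at -6.73 fasted and -7.21 refed, is left out of the panel for scale.

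Glycogen metabolism held 2 of 14 genes that rose in fasted LG2KO livers, the phosphatase subunit Ppp1r3g by 1.86 ± 0.22 and glycogen phosphorylase, Pygl, by 0.97 ± 0.12, with 4 higher and 1 lower when adjusted over the list alone (camera, adjusted p = 0.0156, and adjusted p = 0.379 with an estimated correlation). Cyp2b9 rose by 5.89 ± 0.63, Mmd2 by 2.40 ± 0.39, Dct by 1.71 ± 0.31, Ptgds by 1.66 ± 0.24 and Rrm2, a subunit of ribonucleotide reductase, by 1.82 ± 0.30. Hsd3b5 fell by 2.36 ± 0.34, Cib3 fell by 1.23 ± 0.19, C6 fell by 1.12 ± 0.17, Enho fell by 0.84 ± 0.15, Cyp1a2 fell by 0.81 ± 0.11 and the liver transcription factor Foxa3 fell by 0.68 ± 0.13. Fam89a, Sel1l3 and Pla2g12a fell by 0.71 ± 0.12, 0.68 ± 0.12 and 0.64 ± 0.11.

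Other lists had a camera call in the fasted state that was lost with an estimated correlation. None of 17 cholesterol synthesis enzymes passed, 3 were lower when adjusted over the list alone, and their median was -0.47 (camera, adjusted p = 1.49e-10, and adjusted p = 0.304 with an estimated correlation); Sqle was at -1.42 ± 0.38 and Msmo1 at -1.18 ± 0.26. The 9 male-biased genes had a median of -0.72, with Hsd3b5 passing and 3 lower when adjusted over the list alone (adjusted p = 8.66e-09, and adjusted p = 0.0701 with an estimated correlation). Their median was -0.41 without control fasted replicate 2 and -0.46 without LG2KO fasted replicate 3. The 11 female-biased genes had a median of 0.34, with Cyp2b9 passing and 2 higher and 1 lower when adjusted over the list alone (adjusted p = 0.00373, and adjusted p = 0.309 with an estimated correlation). Their median was 0.19 without control fasted replicate 1 and 0.15 without LG2KO fasted replicate 1. Of 18 genes of gluconeogenesis and amino acid catabolism 3 rose, namely G6pc, Pcx by 0.40 ± 0.07 and Fbp1 by 0.20 ± 0.04, with 4 higher and 2 lower when adjusted over the list alone (adjusted p = 0.0189, and adjusted p = 0.433 with an estimated correlation). Of 16 glycolysis genes Pklr rose, with 3 when adjusted over the list alone, and the median was -0.02 while the mean of 0.18 and the test were positive, with the median at most 0.02 when 1 array was left out (adjusted p = 0.00503, and adjusted p = 0.379 with an estimated correlation). In the cell cycle list Rrm2 was the 1 of 23 that passed, with 2 when adjusted over the list alone (adjusted p = 0.00896, and adjusted p = 0.433 with an estimated correlation). The test of 22 genes of fatty acid oxidation was downward with 0 passing, and 3 lower when adjusted over the list alone (adjusted p = 0.000131, and adjusted p = 0.433 with an estimated correlation).

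Marker lists of other cell types in the fasted comparison depended on single arrays. The 9 exocrine pancreas markers had a median of -1.01 with 0 passing, also when adjusted over the list alone (adjusted p = 2.04e-05, and adjusted p = 0.433 with an estimated correlation), and without control fasted replicate 3 the median was -0.04 (adjusted p = 0.473). It was -1.54 without control fasted replicate 2. The test of 14 endothelial markers was downward with 0 passing, also when adjusted over the list alone (adjusted p = 0.0187, and adjusted p = 0.433 with an estimated correlation), and the call ended without control fasted replicate 3 or LG2KO fasted replicate 3 (at most 0.824).

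In total 72 genes passed in fasted livers, 56 higher and 16 lower in LG2KO, and 946 had an unadjusted p below 0.05. The number 946 is close to what chance alone would give among all genes tested. For all 72 the arrays of the groups did not overlap, which passing nearly fixes, so this adds no support. The count was 93 without the arrays that stand apart, 60 of them among the 72. Array weights gave 203 and a fit of only these groups 44. It was 32 and 36 without control fasted replicates 2 and 3, and 30, 30 and 42 without LG2KO fasted replicates 1, 2 and 3. Of 31 named genes that passed, 16 passed without each array, namely Pklr, Tkfc, Khk, G6pc, Elovl6, Thrsp, Fasn, Me1, Acly, Mid1ip1, Acaca, Ppp1r3g, Pygl, Cyp2b9, Cyp1a2 and Slc2a2, and the other 15 missed without at least 1: 8, 12 and 13 of them without control fasted replicates 1, 2 and 3, and 14, 13 and 11 without LG2KO fasted replicates 1, 2 and 3. Of the lists, glycogen and gluconeogenesis each missed without LG2KO fasted replicate 1 or 2 or control fasted replicate 2 (at most 0.179 and 0.542), cell cycle without LG2KO fasted replicate 2 or control fasted replicate 2 (at most 0.101), fatty acid oxidation without LG2KO fasted replicate 3 (0.112) and female-biased genes without LG2KO fasted replicate 1 (0.112). Without the arrays that stand apart the calls of glycolysis, fatty acid oxidation, cell cycle and endothelial markers ended (adjusted p = 0.062, 0.118, 0.0717 and 0.759).

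Whether feeding altered the genotype effect was tested as an interaction, and Pklr was the 1 gene that passed. The genotype effect on Pklr after refeeding minus that in the fasted state was -1.75 ± 0.16 (adjusted p = 0.0024). Refeeding moved Pklr from 8.85 to 9.78 in controls and from 10.77 to 9.95 in LG2KO. No other gene passed in limma's test. An unadjusted p below 0.05 was found for 861 genes, fewer than chance alone would give among all genes tested. That number thus gives no sign of further interactions. Without the arrays that stand apart the count of genes that passed was again 1. Elovl6 at -1.93 ± 0.38, Idi1 at -2.14 ± 0.45, Hmgcs1 at -1.98 ± 0.42, Acly at -1.23 ± 0.19 and Tkfc at -1.07 ± 0.18 had adjusted p-values of 0.265, 0.369, 0.369, 0.13 and 0.174. The ChREBP-linked list had a median difference of -0.42, with Pklr passing and 1 higher and 6 lower when adjusted over the list alone (camera, adjusted p = 5.96e-09, and adjusted p = 0.0048 with an estimated correlation). The 17 cholesterol synthesis enzymes had a median of -0.67, with 0 passing and 2 lower when adjusted over the list alone (adjusted p = 3.59e-09, and adjusted p = 0.329 with an estimated correlation). Their median was -0.44 without control refed replicate 2. Those 2 enzymes were Idi1 and Hmgcs1, and adjusted over all genes the larger refed fall was not separated from the fasted difference for any enzyme. Leaving out control refed replicate 3 gave 2 genes, as did robust estimation and cyclic loess, while array weights gave 20 and the top 25% of genes by mean 6. Fatty acid synthesis and acute phase genes kept their interaction calls without each array (camera, adjusted p at most 0.00443 and 0.0128). Both calls were lost with an estimated correlation. The remaining lists lost their interaction calls without single arrays. Glycogen did so without control refed replicate 1 (0.0564). Macrophage markers did so without LG2KO fasted replicate 3, LG2KO refed replicate 3, control fasted replicate 1 or control refed replicate 2 (at most 0.463). The stress response missed without LG2KO fasted replicate 3, LG2KO refed replicate 2 or 3 or control refed replicate 2 or 3 (at most 0.436). Exocrine pancreas markers missed without LG2KO fasted replicate 2 or 3, control refed replicate 2 or 3 or control fasted replicate 3 (at most 0.976).

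Averaged over the feeding states, 185 genes differed by genotype, 134 higher and 51 lower in LG2KO, with 1612 at an unadjusted p below 0.05. Named genes that passed in this average and are not described above were the steroid hydroxylase gene Cyp17a1 at 1.52 ± 0.27 and Ly6d at 1.36 ± 0.23, both higher, and Sqle at -1.47 ± 0.27, the aldehyde oxidase Aox3 at -1.08 ± 0.21 and the acetyltransferase Nat8 at -0.82 ± 0.16, all lower. Of the lists, 8 of 17 cholesterol synthesis enzymes fell (16 when adjusted over the list alone), 9 of 20 fatty acid synthesis genes rose and 1 fell (11 and 1), 8 of 15 ChREBP-linked genes rose and Slc2a2 fell (11 and 1), and 4 of 9 male-biased genes fell (8 when adjusted over the list alone). These had adjusted p-values of 0.0256, 0.0191, 0.00173 and 0.0191 with an estimated correlation. Another 11 lists had a camera call that was lost with an estimated correlation, at adjusted p-values of 0.0746 to 0.494. Of these, 7 also ended without single arrays: gluconeogenesis without control fasted replicate 2 (0.0512), xenobiotic metabolism without control refed replicate 1 (0.133), exocrine pancreas markers without control fasted replicate 3 (0.319), glycolysis without LG2KO refed replicate 3, control fasted replicate 2 or control refed replicate 1 (at most 0.101), and bile acid synthesis without LG2KO fasted replicate 3, LG2KO refed replicate 3, control fasted replicate 2 or control refed replicate 1 (at most 0.185). Cell cycle genes missed without LG2KO fasted replicate 2, LG2KO refed replicate 1, control fasted replicate 2 or 3 or control refed replicate 1 or 3 (at most 0.21), and hepatocyte markers without LG2KO fasted replicate 2 or 3, LG2KO refed replicate 3, control fasted replicate 1 or 2 or control refed replicate 1 (at most 0.345). In the fit without the arrays that stand apart 235 genes passed, 150 of them among the 185. Array weights gave 443 and no intensity trend 122. The count was 122, 120 and 117 without LG2KO refed replicates 1, 2 and 3, 90 and 107 without control fasted replicates 2 and 3, and 103, 88 and 105 without LG2KO fasted replicates 1, 2 and 3. Of 47 named genes that passed, 31 passed without each array. The other 16 missed without at least 1, and 14 of them did so without control fasted replicate 2. For 144 of the 185 genes the arrays of the genotypes did not overlap in either feeding state.

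The genotype effects in the 2 feeding states compare different arrays, and their calls overlapped. Both share each gene's estimate of spread from the 1 fit, so the calls are not independent. The numbers for independent lists below are thus not the overlap that chance would give. Of the genes higher in LG2KO, 17 passed in both states, against 0.163 for independent lists, and 4 were lower in both, against 0.0141. The higher ones included Cyp2b9, Mmd2, Dct, Ptgds, Kbtbd11, Srebf1, Khk, Pcx and Fbp1, and the lower ones were Slc2a2, Hsd3b5, Cib3 and C6. No gene passed in opposite directions. Across genes, which are not independent replicates, the fold changes correlated at r = 0.352 and rho = 0.143, and r lay between 0.0401 and 0.507 when 1 array was left out.

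Refeeding of control mice, the reference for the response to food, raised genes of sterol and fatty acid synthesis and lowered genes of gluconeogenesis and lipoprotein handling. The sterol pathway genes Mvd, Sqle, Fdps, Idi1, Hmgcs1 and Cyp51 rose by 3.54 ± 0.31, 3.53 ± 0.38, 3.51 ± 0.35, 3.24 ± 0.32, 3.16 ± 0.30 and 2.76 ± 0.31. Of 17 enzymes of this list 15 rose, 16 when adjusted over the list alone, with a median of 2.32 (camera, adjusted p = 5.07e-26, and adjusted p = 0.0257 with an estimated correlation). Fasn rose by 2.64 ± 0.16, Mid1ip1 by 2.24 ± 0.10, Srebf1 by 1.38 ± 0.10 and Acly by 1.16 ± 0.13, and 8 of 20 fatty acid synthesis genes rose, with 9 higher and 1 lower when adjusted over the list alone (adjusted p = 5.48e-10, and adjusted p = 0.0188 with an estimated correlation). Pklr rose by 0.92 ± 0.12, and Angptl8, a feeding-induced regulator of lipoprotein lipase, by 2.97 ± 0.33. The metallothionein genes Mt2 and Mt1 fell by 4.38 ± 0.32 and fell by 3.86 ± 0.28, and the glucocorticoid-responsive gene Fkbp5 fell by 2.14 ± 0.22.

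Genes of glucose production also fell on refeeding in controls. The aminotransferase Got1 fell by 2.09 ± 0.15, Gpt2 fell by 0.87 ± 0.10, their activator Foxo1 fell by 0.75 ± 0.13 and Pck1, the first committed enzyme of the path, fell by 0.72 ± 0.16, while G6pc was at -0.23 ± 0.15 with an adjusted p of 0.542. Of 18 genes of gluconeogenesis and amino acid catabolism 9 fell, 14 when adjusted over the list alone (camera, adjusted p = 2.73e-15, and adjusted p = 0.0211 with an estimated correlation). Of 23 genes of lipoprotein and triglyceride handling 7 fell, 9 when adjusted over the list alone, and Lpin1, a regulator of fat metabolism, fell by 1.53 ± 0.18 (list adjusted p = 1.78e-05, and adjusted p = 0.0188 with an estimated correlation). In the stress response list 11 of 20 genes rose and 2 fell, 12 and 2 when adjusted over the list alone (adjusted p = 6.58e-10, and adjusted p = 0.0188 with an estimated correlation). The endoplasmic reticulum genes Sdf2l1, Creld2, Hyou1 and Pdia4 rose by 2.51 ± 0.14, 2.50 ± 0.19, 1.78 ± 0.12 and 1.08 ± 0.09. Cpt1a, which admits fatty acids to mitochondria, fell by 1.30 ± 0.11 and the lipase gene Pnpla2 fell by 1.37 ± 0.10.

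Further lists in refed controls had a camera call that was lost with an estimated correlation. Fatty acid oxidation had 5 of 22 lower, 6 when adjusted over the list alone (adjusted p = 0.292 with an estimated correlation). Male-biased genes had 3 of 9 higher, 3 when adjusted over the list alone (adjusted p = 0.292 with an estimated correlation), with Hsd3b5 up by 2.77 ± 0.34. Glycolysis had 1 of 16 higher, 1 when adjusted over the list alone (adjusted p = 0.351 with an estimated correlation). Acute phase genes had 3 of 26 lower, 3 when adjusted over the list alone, among them Lbp at -0.60 ± 0.08 (adjusted p = 0.556 with an estimated correlation). Circadian clock genes had 1 of 18 higher and 3 lower, 1 and 5 when adjusted over the list alone (adjusted p = 0.245 with an estimated correlation). Exocrine pancreas markers had a median of -0.98 and 0 passing, also when adjusted over the list alone (adjusted p = 0.556 with an estimated correlation), and without control fasted replicate 3 the median was -0.08 (adjusted p = 0.682). Moxd1, which fell by 2.57 ± 0.63, was also highest on that array, at 9.01 against at most 7.48 elsewhere. Acute phase genes missed without control fasted replicate 1 or 3 or control refed replicate 3 (at most 0.251), and clock genes without control fasted replicate 3 or control refed replicate 2 or 3 (at most 0.220).

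In total 1176 genes passed on refeeding in controls, 599 higher and 577 lower, with 3038 at an unadjusted p below 0.05. Without the arrays that stand apart 2202 passed, 1123 of them among the 1176. Array weights gave 2454 and a fit of only these groups 695. The count was 758 and 742 without control refed replicates 2 and 3 and 706 and 747 without control fasted replicates 1 and 2. Falls outnumbered rises without control refed replicate 2 (422 and 336) and without control fasted replicate 2 (387 and 360). Of 75 named genes that passed, 63 passed without each array and the other 12 missed without at least 1: 8, 7 and 5 without control fasted replicates 1, 2 and 3, and 0, 7 and 4 without control refed replicates 1, 2 and 3. Moxd1 and Pck1 were among these 12.

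Refeeding of LG2KO mice raised sterol synthesis, as in controls, while several ChREBP-linked genes fell. Sqle, Mvd and Fdps rose by 3.43 ± 0.38, 2.99 ± 0.31 and 2.73 ± 0.35, and 13 of 17 enzymes rose, 15 when adjusted over the list alone, with a median of 1.17 (camera, adjusted p = 9.76e-14, and adjusted p = 0.0932 with an estimated correlation). Pklr fell by 0.82 ± 0.12 (adjusted p = 0.000982), G6pc fell by 1.05 ± 0.15 and Txnip fell as well (adjusted p = 0.000569). Of 15 ChREBP-linked genes 6 fell and 2 rose, 8 and 3 when adjusted over the list alone, with a median of -0.46 (adjusted p = 0.00105, and adjusted p = 0.0358 with an estimated correlation). In controls 5 of these genes rose and 2 fell, and the interaction given above tests that difference. Fasn, Srebf1 and Mid1ip1 rose by 1.65 ± 0.16, 1.65 ± 0.10 and 1.33 ± 0.10, with 4 of 20 fatty acid synthesis genes higher, 5 when adjusted over the list alone (adjusted p = 0.000517, and adjusted p = 0.0932 with an estimated correlation).

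Much of the remaining response was shared with controls. Of 18 genes of gluconeogenesis and amino acid catabolism 10 fell, 14 when adjusted over the list alone, such as Got1, which fell by 1.60 ± 0.15 (adjusted p = 0.0347 with an estimated correlation). Of 23 genes of lipoprotein and triglyceride handling 7 fell, 8 when adjusted over the list alone (adjusted p = 0.0347 with an estimated correlation), and Lpin1 fell by 2.15 ± 0.18. The stress response list had 10 of 20 higher and 2 lower, 14 and 2 when adjusted over the list alone (adjusted p = 0.0347 with an estimated correlation), and Creld2, Sdf2l1 and Derl3 rose by 3.09 ± 0.19, 2.97 ± 0.14 and 2.90 ± 0.29. Mt2 and Mt1 fell by 2.62 ± 0.32 and fell by 2.33 ± 0.28, the glycogen-targeting gene Ppp1r3g fell by 2.07 ± 0.22, and Cpt1a fell by 1.18 ± 0.11. Genes called in both genotypes in the same direction were 392 higher and 284 lower, against 27.9 and 13.8 for independent lists, and 1 passed in opposite directions, Pklr. These calls share each gene's estimate of spread, so 27.9 and 13.8 are not the overlap that chance would give. Across genes, which are not independent replicates, the refeeding responses of the genotypes correlated at r = 0.684 and rho = 0.482.

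Further lists in refed LG2KO livers had a camera call that was lost with an estimated correlation. Fatty acid oxidation had 4 of 22 lower, 6 when adjusted over the list alone (adjusted p = 0.133 with an estimated correlation), and glycogen metabolism 3 of 14 lower, 6 when adjusted over the list alone (adjusted p = 0.0932 with an estimated correlation). Bile acid synthesis had 3 of 13 lower, such as Cyp8b1, which fell by 1.07 ± 0.15, and 1 higher, with the same numbers when adjusted over the list alone (adjusted p = 0.299 with an estimated correlation). Xenobiotic metabolism had 2 of 23 higher and 4 lower, also when adjusted over the list alone (adjusted p = 0.0921 with an estimated correlation). Interferon genes had 2 of 17 higher, 3 when adjusted over the list alone, with Oasl1 up by 1.07 ± 0.16 (adjusted p = 0.485 with an estimated correlation). Clock genes had 1 of 18 higher and 3 lower, 1 and 5 when adjusted over the list alone (adjusted p = 0.161 with an estimated correlation), and the test of 14 macrophage markers was upward with 0 passing, also when adjusted over the list alone (adjusted p = 0.657 with an estimated correlation). Bile acid synthesis missed without LG2KO fasted replicate 1 or 2 or LG2KO refed replicate 3 (at most 0.153), clock genes without LG2KO fasted replicate 1 or 2 or LG2KO refed replicate 1 or 3 (at most 0.142), interferon genes without LG2KO fasted replicate 3 (0.177), and macrophage markers without that array or LG2KO refed replicate 1 or 3 (at most 0.552). Without the arrays that stand apart the interferon and macrophage calls ended (adjusted p = 0.231 and 0.6).

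In total 1283 genes passed on refeeding in LG2KO, 847 higher and 436 lower, with 3307 at an unadjusted p below 0.05. Without the arrays that stand apart 3187 passed, 1269 of them among the 1283. The excess of rises was lost there, with 1408 higher and 1779 lower, and also among the 3578 genes that passed with array weights (1778 and 1800) and without LG2KO fasted replicate 3 (757 and 750). The count was 713 and 697 without LG2KO refed replicates 2 and 3 and 716 and 770 without LG2KO fasted replicates 1 and 2. Of 72 named genes that passed, 59 passed without each array and the other 13 missed without at least 1: 11, 10 and 4 without LG2KO fasted replicates 1, 2 and 3, and 9, 11 and 10 without LG2KO refed replicates 1, 2 and 3.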

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

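The tests on RNA degradation, feeding labels, Xist, tamoxifen labels and pancreas tissue were chosen only after the result was seen. A test of the interaction singled out Pklr and 8 gene lists whose genotype effect differed between the feeding states. Pklr differed by -1.75 and the ChREBP-linked list by a median of -0.42 (without Slc2a2 it was -0.41). The cholesterol synthesis list differed by -0.67, the fatty acid synthesis list by -0.0588 with a mean of -0.31, and the glycogen list by -0.28 (adjusted p = 0.329, 0.266 and 0.329 with an estimated correlation). The stress response list differed by 0.16, the acute phase list by 0.26, the macrophage markers by 0.25 and the exocrine pancreas markers by 0.91 (adjusted p = 0.376, 0.376, 0.698 and 0.826 with an estimated correlation). Leaving out 1 array moved these medians, for cholesterol synthesis from -0.99 to -0.44 (the latter without control refed replicate 2), fatty acid synthesis from -0.18 (without LG2KO fasted replicate 3) to 0.05 (without LG2KO refed replicate 2), glycogen from -0.45 (without LG2KO fasted replicate 3) to -0.18 (without control fasted replicate 2) and the stress response from 0.09 (without LG2KO fasted replicate 3) to 0.30 (without LG2KO fasted replicate 1). Acute phase went from 0.16 (without control refed replicate 3) to 0.44 (without control fasted replicate 2), macrophage markers up to 0.45 (without LG2KO refed replicate 2) and exocrine pancreas markers from 0.00295 (without control fasted replicate 3) to 1.43 (without control fasted replicate 2). Among probe sets without a single gene symbol, which no gene comparison uses, 23 differed between LG2KO and control averaged over feeding, 19 of them higher, with a largest rise of 3.73.

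Control refed replicate 1 and LG2KO fasted replicate 3 lay far from their groups, in opposite directions on the second component. Cyclic loess left control refed replicate 1 at a root mean square distance of 0.474 from the rest of its group against at most 0.327 for the 10 other arrays, which argues against a smooth intensity-dependent difference as the whole cause. RNA degradation is argued against by the 3' minus 5' differences of control transcripts, of which 0 of 3 lay outside the range of the 10 other arrays by over 0.1. Actb and Pcx lay within that range on both arrays. For Gapdh the range, -0.138 to -0.061, was narrower than this margin, and control refed replicate 1 lay just above it at -0.055. Swapped feeding labels are argued against by positions of 0.809 and 0.0168 on the axis from fasted (0) to refed (1). The other refed controls lay higher on that axis, at 1.06 and 1.05. Across probe sets control refed replicate 1 correlated best with a fasted array, LG2KO fasted replicate 1, at 0.989. Its highest correlation within its own group was 0.987. A difference in hybridisation or in the animals pooled may remain and was not tested.

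Cyp2b9 was higher and Hsd3b5 lower in LG2KO livers in both feeding states. The male-biased list had 2 of 9 genes lower refed and 1 of 9 fasted (adjusted p = 0.0381 refed and 0.0701 fasted with an estimated correlation). Female animals in the LG2KO pools are argued against by Xist, whose averaged log2 difference had an upper 95% bound of 0.25. Dependence on the arrays that stand apart is argued against by the male-biased median of -0.49 without them. All 6 LG2KO arrays and 0 control arrays are labelled as tamoxifen treated, and the labels do not say whether control mice also received it. An effect of tamoxifen cannot be told apart here from the loss of Slc2a2, because the labels of both coincide on every array. The pattern could come from either, and a biological effect of genotype stays open.

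Exocrine pancreas transcripts were high on control fasted replicate 3. All 9 measured markers lay over 1 above every other array on the log2 scale, with Ctrb1 at 9.18 and Prss2 at 8.28, so a candidate source is pancreas tissue in 1 pool. Skeletal muscle transcripts such as Ckm, at 7.32 against at most 5.72 elsewhere, were high on the same array, so other tissue may have come along as well. Across the arrays 21 genes lay over 1 above all others on this array, against 0 to 13 on the others. The group design gives no biological explanation to test for a single array.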

How the results depend on the processing

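The fit without the arrays that stand apart was chosen after seeing the data, and the cause of the changes below was not tested unless stated. Slc2a2 passed under each alternative that kept it (the top 25% of genes by mean does not hold it), at -7.38 to -7.04 refed and -7.05 to -6.51 fasted. Of 253 other named values that passed, 0 changed sign; 173 passed without each array, 253 with array weights, 246 after cyclic loess, 240 after centring, 230 as the mean of all probe sets, 219 without the intensity trend and 230 without the arrays that stand apart. Counts are given in the order refed, fasted, control refeeding, LG2KO refeeding, interaction, average, where they moved by over 1.5 times. Array weights gave 180, 203, 2454, 3578, 20 and 443. No intensity trend gave 41 refed and 122 in the average; robust estimation 43 refed and 2 for the interaction; the brightest genes (top 25% by mean) 121 refed and 6 for the interaction, with fewer genes tested. Only the groups compared gave 15, 44 and 695, with fewer arrays behind the spread. An adjusted p below 0.01 gave 6, 31, 568, 563 and, in the average, 60, and a fold of 1.5 gave 658, 674 and 92, as stricter thresholds must lower counts. Cyclic loess gave 2 for the interaction, and without the arrays that stand apart refeeding gave 2202 and 3187. Leaving out 1 array, which leaves fewer arrays, gave 8 to 46, 30 to 48, 706 to 1467, 697 to 1507, 1 to 2 and 88 to 207. Lists with a call numbered 3, 2, 5, 4, 1 and 4 with an estimated correlation, against 11, 12, 11, 13, 8 and 15. Directional fry gave 6, 4, 1 and 7 refed, fasted, for the interaction and in the average, and mixed fry 24 and 23 on refeeding and 4 for the interaction. The top 50% of genes by mean gave 7 in control refeeding and 5 for the interaction, and the fit without the arrays that stand apart 5 for the interaction. Leaving out 1 array gave 7 to 13 lists refed and 5 to 9 for the interaction. The interaction of exocrine pancreas markers ranged from 0.00295 without control fasted replicate 3, the array with these transcripts, to 1.43 without control fasted replicate 2, and in the former its test changed sign. No label says that the replicate numbers pair arrays across groups. Deviations of same-numbered arrays correlated at -0.464 to 0.769, over 0.1 in 6 of 18 pairs. Arrays with different numbers were not compared in this way, so these values do not decide on pairing. With the replicate number as a block the interaction gave 6 genes, and the other 5 counts moved by less than 1.5 times. Signal over background cannot be given from summarised values, which limits statements on dim genes.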

Other observations

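The test of p53 targets was chosen after Cdkn1a had been seen, and its list was written before its result. The lists of insulin signalling, hexose transporters and sterol uptake had no camera call in any comparison with all arrays. Without the arrays that stand apart insulin signalling had one on refeeding in controls and in LG2KO (adjusted p = 0.00733 and 0.012), and directional fry called hexose transporters in the fasted state and in the average (adjusted p = 0.0345 and 0.0068) and insulin signalling on refeeding of controls (adjusted p = 0.0324). Single members passed. Slc2a2 fell with genotype in both feeding states, and 1 hexose transporter fell on refeeding in each genotype. Of insulin signalling genes 1 rose with genotype in refed livers, 3 fell on refeeding in controls, and 2 rose and 3 fell on refeeding in LG2KO. Of sterol uptake genes 1 fell in the genotype average, and 3 rose and 4 fell on refeeding in each genotype. Averaged over feeding, the median genotype difference was -0.15 for 18 insulin signalling genes (camera, adjusted p = 0.128), -0.01 for 13 hexose transporters with a mean of -0.49 through Slc2a2 (adjusted p = 0.402), 0.00 for 13 genes of sterol uptake and its regulation (adjusted p = 0.353) and 0.02 for 20 genes of bile acid transport (adjusted p = 0.886). Sex chromosome transcripts had a median of 0.01 over 4 genes (adjusted p = 0.813), and lipoprotein genes 0.02 over 23 (adjusted p = 0.656).

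Marker lists of other liver cells had no camera call in the genotype average, apart from hepatocytes and exocrine pancreas. Macrophage markers had a median of 0.27 refed (adjusted p = 0.0425, and adjusted p = 0.717 with an estimated correlation) and -0.11 fasted (adjusted p = 0.177). The fasted test did not pass, so an opposite sign is not established. Relative to all arrays these markers lay on average at 0.31 on control fasted replicate 1 and -0.31 on LG2KO fasted replicate 3. The other fasted arrays lay between -0.14 and 0.03. The refed median was 0.08 without LG2KO refed replicate 3 and 0.41 without replicate 2, and 1 cholangiocyte marker rose in the fasted state. The averaged median was 0.01 for stellate cells and fibroblasts (adjusted p = 0.116), 0.09 for cholangiocytes (adjusted p = 0.314), 0.09 for macrophages (adjusted p = 0.465), 0.06 for lymphocytes and neutrophils (adjusted p = 0.43), 0.03 for erythroid cells (adjusted p = 0.465), 0.13 for adipose tissue (adjusted p = 0.408) and -0.05 for endothelium (adjusted p = 0.0624). On LG2KO refed replicate 2 the adipose markers lay on average 0.71 above their mean over all arrays, against at most 0.13 on any other array. The cause was not tested. The 11 hepatocyte markers had a median of -0.05 (adjusted p = 0.0407, and adjusted p = 0.182 with an estimated correlation), and the call ended without the arrays that stand apart (adjusted p = 0.678). Without those arrays the stellate cell and fibroblast, interferon and bile acid transport lists passed (adjusted p = 0.0041, 0.000615 and 0.0326).

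Cdkn1a and Phlda3, the latter chosen after its values were seen, are p53 targets, and both were higher in refed LG2KO livers, by 1.59 ± 0.27 and 0.94 ± 0.12. A wider p53 response might follow, and 22 other measured targets were tested. Their median averaged difference was 0.07, with 0 passing and a camera p of 0.145 with an estimated correlation. The 95% interval of their mean, -0.04 to 0.19, leaves a small shift open.

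Other splits of the arrays were refitted to see how many genes chance groupings give. For each comparison of 3 arrays with 3 there are 10 splits, too few for a share below 0.05. The real splits gave 69, 72, 1176 and 1283 genes, the only 1 of 10 to reach that count in each case, against at most 1, 0, 0 and 0 in another. For the genotype effect averaged over feeding, 1 of 100 drawn splits, the real one with 185 genes, reached that count and the highest other gave 6. The real split was always among the 100, so no smaller share was possible. This makes chance an unlikely source of that count but does not exclude it. It does not speak to single genes or to other differences between the genotype groups. For the interaction 12 of 100 drawn splits gave at least the real count of 1 and the highest other gave 6. All 11 other splits with a gene keep the real genotype groups in 1 feeding state, which turns that state's genotype effect into an interaction, so this count of splits does not decide on chance. Of the 79 drawn splits that keep the real groups in neither state, 0 gave a gene.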
